A study of Phyllostachys violascens with 16 samples.

How the data were processed

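Total RNA was sequenced from the middle part, about 10 cm long, of young spring shoots of Lei bamboo (Phyllostachys violascens), a bamboo grown for its edible shoots. Per the labels, shoots of 30 to 40 cm were packed in polyethylene bags at 60 to 70% humidity and kept at 4 °C, with 30 shoots together in each repeat. Segments of 6 shoots were sampled for each repeat at 0, 2, 6 and 20 days, so each library is a pool. The 16 libraries form 4 groups of 4 biological replicates, called 0d, 2d, 6d and 20d here. Whether the stored shoots were kept in the light or in the dark is not stated. The series holds no shoots kept at another temperature. The effect of cold therefore cannot be told apart from that of time since harvest or of packing.

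The authors deposited 1 table of 50936 genes with the FPKM and the count of each gene in each library. Per the file headers the first block holds FPKM, which scales fragments by gene length and library size and in which a value of 0 is written as 0.0001. As deposited by the authors, the counts are estimated counts that were not normalised: they are whole numbers, but 4 is the most frequent count above 0 and 8 the next, and 35.2% of the counts from 1 to 19 are multiples of 4. A sequenced fragment therefore seems to add about 4 deposited counts, and counting limits below use fragments of 4 counts. The aligner, the counting tool and the genome build are not given in the sources used here. Gene positions are those the deposited table lists, on numbered scaffolds. Gene names are the descriptions of best database hits in that table, which 49347 genes have. They name the closest described protein and not the function of the bamboo gene.

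The deposited total count per library ranged from 51.7 to 64.9 M. A gene with 0 counts in all 4 libraries of a group was given a floor of 3 fragments, 12 deposited counts, over the group, and its ratio is printed as a lower bound. Where a group held 1 to 3 fragments, the ratio is printed with an exact 95% Clopper-Pearson interval on fragments. A fractional sum in that group, also one below 1 fragment, was rounded up to whole fragments for the interval. The ratio itself used the sum as it stood. These floors and intervals cover counting error only, since the reads carry no molecular identifiers.

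The 24944 genes with a mean FPKM of at least 1 over all libraries were tested. Counts were scaled by TMM factors and fitted in edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood method with a trended prior and robust estimates, with the 4 times as 4 groups. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 with an absolute log2 change of at least 1. Each stored time was compared with 0d, and successive stored times with each other. An F test over the 4 times was called at the same limits, using the largest difference between any pair of times. The printed error of a log2 change is its standard error (SE). Before the data were examined the test had been fixed as limma on log2(FPKM + 1), with edgeR named as the main test should counts be present. As the table holds counts, edgeR was used, and limma 3.58.1 on log2(FPKM + 1) was added as an alternative after the data were seen. On simulated libraries with 50 changed genes per step, 94% of the genes changed by 1 on the log2 scale and 7 unchanged genes passed by adjusted p alone in edgeR. With the limit on the log2 change as well, 0 unchanged genes were called. Every simulated gene had the same low dispersion, which made genes with few counts less variable than in the deposited libraries. These simulated results may therefore be better than those on the real data.

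A total of 55 gene lists were fixed as patterns on the descriptions before the data were examined. They were tested by the camera procedure of limma with a preset inter-gene correlation of 0.01, and again with an estimated correlation, over the 54 lists with at least 5 tested members; the polyphenol oxidases had 0 members. Benjamini-Hochberg adjustment was over the lists of a comparison. In 161 of 162 list results against 0d the count of called members adjusted over the list alone equalled that over all genes tested. In the other it differed by 1 gene. The descriptions let some stray genes into the lists, and a version without them was added after the data were seen.

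The genes named were chosen by a rule fixed before the data were examined. For each comparison with 0d it takes the 6 called genes with the largest rise and the 6 with the largest fall, among those with a mean FPKM of at least 5, an informative description and no overlap between the libraries of the groups compared. In each list described it takes the 2 called members with the smallest adjusted p, and in each enzyme family of lignin and cellulose synthesis the member with the highest mean FPKM, whatever its test gives. For successive times it takes the 3 largest rises and 3 largest falls.

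The alternatives were DESeq2 1.42.0, median-of-ratios, total-count and quantile scaling, other filters and pseudocounts, other variance models and fold thresholds, a replicate block, array weights, fits on the compared groups alone, each library or replicate number left out, and other list tests. Total-count scaling, counts divided by 4 and the lists without strays were also chosen after seeing the data. Pathways listed in the deposited table were tested by a hypergeometric test among the 9109 tested genes that have one. No deposited library was left out. Figures were drawn with matplotlib.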

Results

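The table holds 16 libraries of Lei bamboo shoot segments, 4 at each of 0, 2, 6 and 20 days of storage at 4 °C. Total counts per library, in M (mega), were 54.3 to 64.9 M at 0d, 51.7 to 62.4 M at 2d, 51.9 to 64.1 M at 6d and 51.7 to 63.8 M at 20d. Unless stated otherwise, values are mean FPKM ± SD over n = 4 libraries, and changes are log2 changes with their SE and adjusted p from edgeR. At 0d a library held 25768 ± 51.5 genes with an FPKM of at least 1 (n = 4), against 23046 ± 22.8 at 2d, 23342 ± 97.6 at 6d and 22758 ± 26.0 at 20d. The 10 genes with most counts took 2.03% of a library at 0d, 4.00% at 2d, 2.55% at 6d and 2.43% at 20d. Replicates lay close together for the 11339 tested genes with a mean FPKM of at least 10. Their median coefficient of variation was between 4.02% and 4.45% across the times. Genes below that level are not covered by it.

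**Figure D1:**
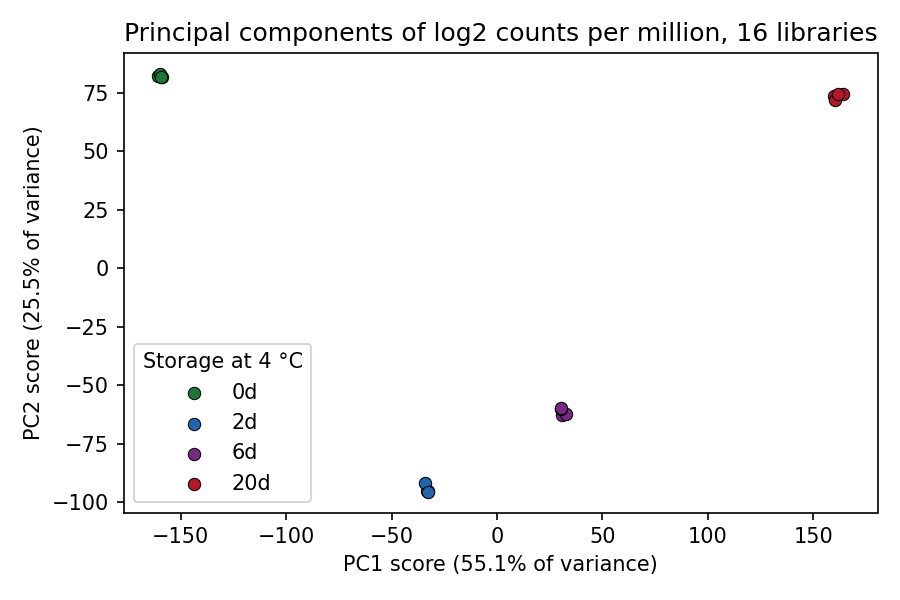
Scores of the 16 libraries on the first 2 principal components of log2 CPM; each point is a library, coloured by storage time, and axis labels give the share of variance in percent. The libraries form 4 clusters, with mean PC1 scores of -160 at 0d, -33.1 at 2d, 31.1 at 6d and 162 at 20d.

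The first comparison asks which transcripts changed during the first 2 days of cold storage. Genes of cellulose synthases, xyloglucan endotransglucosylases, arabinogalactan proteins and photosynthesis were lower at 2d than at 0d, and genes of amino acid breakdown and autophagy were higher. Glutamate dehydrogenase A-like (PH02Gene27470), an enzyme that releases ammonium from glutamate, rose from 98.5 ± 2.26 to 649 ± 16.1 FPKM (log2 change 2.97, SE 0.02, n = 4, edgeR adjusted p = 2.17e-43). The cellulose synthase A catalytic subunit 3 gene (PH02Gene49673) fell from 139 ± 1.91 to 25.1 ± 0.771 FPKM. Of the 24944 genes tested, 7777 were called, 3260 higher and 4517 lower at 2d.

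Among the fixed lists of wall genes 5 passed, all downward. Expansins (adjusted p = 0.0968), enzymes of lignin monomers (0.572), laccases (0.73) and class III peroxidases (0.572) did not pass, nor did the regulators of secondary walls (0.8, direction up). Of the 8 genes in the list of regulators 0 rose and 2 fell. Without strays only 2 genes remained, too few for the list test, and 2 fell (median -3.35). Of 19 cellulose synthase genes 13 fell and 0 rose (median log2 change -1.09, camera adjusted p = 4.38e-05), among them PH02Gene20766, from 111 ± 1.25 to 29.0 ± 0.539 FPKM. All 13 xyloglucan endotransglucosylase genes that were called, of 16, fell (median -3.30, adjusted p = 0.0017). These enzymes cut and rejoin xyloglucan chains. PH02Gene02744 dropped from 33.3 ± 1.75 to 0.361 ± 0.138 FPKM and PH02Gene31368 changed by -3.81 (SE 0.07). Arabinogalactan protein genes, which encode wall glycoproteins, fell in 17 of 19 cases with 0 rises (median -2.52, adjusted p = 9.26e-05), including fasciclin-like arabinogalactan protein 15 (PH02Gene42855, log2 change -3.80, SE 0.08) and 16 (PH02Gene15190, -2.21, SE 0.05). Of 36 genes of xylan synthesis 16 fell and 3 rose (adjusted p = 0.00423, and adjusted p = 0.0586 with an estimated correlation). The trichome birefringence-like 34 gene (PH02Gene47166) changed by -2.27 (SE 0.04) and the xylan glucuronosyltransferase 1-like gene (PH02Gene07859) by -1.54 (SE 0.03). Of 39 genes of pectin remodelling 21 fell and 5 rose (adjusted p = 0.0332), with a pectin acetylesterase 12-like gene (PH02Gene02441) down from 74.9 ± 2.61 to 8.12 ± 0.501 FPKM and a polygalacturonase (PH02Gene00883) from 49.4 ± 0.967 to 11.4 ± 0.101 FPKM. The pectin list lost its call under total-count scaling (adjusted p = 0.144) and with a minimum FPKM of 5 (adjusted p = 0.484).

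Tubulin genes, which encode the subunits of microtubules, fell in 8 of 21 cases and rose in 3 (adjusted p = 0.0367, but adjusted p = 0.302 with an estimated correlation). Tubulin alpha-2 (PH02Gene36495) was at 30.7 ± 0.592 FPKM at 0d and 0.915 ± 0.167 at 2d, and tubulin beta-4 (PH02Gene37926) at 81.7 ± 1.06 and 15.1 ± 0.797. Of 74 photosynthesis genes 50 fell and 4 rose (median log2 change -2.72, adjusted p = 9.60e-06). This list holds 14 subunits of the chaperonin that folds Rubisco, and without such strays 45 of 60 genes fell and 3 rose. A chlorophyll a-b binding protein 2 gene (PH02Gene49412), which encodes a light-harvesting antenna protein, fell from 127 ± 4.68 to 8.09 ± 0.366 FPKM. A photosystem II 10 kDa polypeptide gene (PH02Gene09620) fell from 63.2 ± 2.25 to 0.555 ± 0.131 FPKM. Among 159 genes of heat shock proteins and chaperones 70 fell and 9 rose (median -0.80, adjusted p = 0.000306). The 70 kDa heat shock protein-like gene PH02Gene32604 changed by -4.65 (SE 0.05) and the chloroplastic 25.3 kDa heat shock protein gene PH02Gene22094 by -3.17 (SE 0.05). Glutathione S-transferases, which join glutathione to reactive compounds, fell in 33 of 64 cases and rose in 6 (adjusted p = 0.00121, and adjusted p = 0.0555 with an estimated correlation). The abundant F10-like gene PH02Gene28681 fell from 550 ± 7.79 to 64.8 ± 1.80 FPKM, while GSTF1 (PH02Gene33266) rose from 346 ± 4.23 to 748 ± 16.5 FPKM, a rise below the limit of 1 under quantile scaling (log2 change 0.80).

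Genes of amino acid catabolism and asparagine synthesis rose in 13 of 32 cases with 0 falls (median 0.71, adjusted p = 9.60e-06). With glutamate dehydrogenase, a branched-chain amino acid aminotransferase 2-like gene (PH02Gene19153), whose product starts the breakdown of leucine, isoleucine and valine, rose from 27.2 ± 0.486 to 257 ± 8.78 FPKM. Of 45 autophagy genes 12 rose and 1 fell (median 0.70, adjusted p = 9.60e-06). The atg7 gene (PH02Gene40863), which encodes the activating enzyme of autophagosome formation, rose from 31.0 ± 1.09 to 104 ± 0.480 FPKM, and the 18h-like gene (PH02Gene27630) from 35.2 ± 1.12 to 104 ± 2.39 FPKM. The 83 proteasome genes passed the list test upward (adjusted p = 0.0287) with 5 members called higher and 4 lower, and a median of 0.23 that became -0.02 under total-count scaling, where the adjusted p was 0.292. The S10B subunit (PH02Gene38452) had a log2 change of 1.04 (SE 0.03) and subunit 13 (PH02Gene03953) 1.34 (SE 0.03). The former was below the limit of 1 under 7 of 32 alternatives, down to 0.74, and the latter under 1, at 0.997.

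The largest rises at 2d began near 0. The DMP2 gene (PH02Gene26343, scaffold 10, 3180343 to 3181110) had 0 counts at 0d and was at 4.14 ± 0.856 FPKM at 2d, at least 67.6-fold higher. A wound-induced proteinase inhibitor WIP1-like gene (PH02Gene11536) was at least 65.6-fold and dehydrin DHN3 (PH02Gene07646) at least 9.38-fold higher. In the limma fit on log2(FPKM + 5) none of these 3 was called, with log2 changes of 0.866, 0.905 and 0.125, and DHN3 was not called in 4 of 32 alternatives. A GDAP2 homolog (PH02Gene00521), a LURP-one-related 2-like gene (PH02Gene46062) and an alpha-amylase/trypsin inhibitor gene (PH02Gene19402) rose to 14.2 ± 2.32, 14.2 ± 1.16 and 13.2 ± 1.49 FPKM. The strigolactone esterase D14 gene (PH02Gene24299, scaffold 21, 100100086 to 100101067), which encodes a strigolactone receptor, had 53.4 ± 1.49 FPKM at 0d and 0 counts at 2d, at least 377-fold lower. A bHLH35-like factor (PH02Gene51458), an RHA2A-like ubiquitin ligase (PH02Gene01469) and the jasmonate repressor TIFY 11e (PH02Gene27187) were at least 664-fold, 181-fold and 166-fold lower. A second bHLH35-like gene (PH02Gene12145) had 1 fragment at 2d and a ratio of 3440 (95% interval 616 to 136000), and cytochrome P450 94C1 (PH02Gene18648) had 2 fragments and a ratio of 756 (209 to 6240). Without 2d replicate 1, which held its fragment, PH02Gene12145 was at least 869-fold lower. The fitted changes of PH02Gene00521 and PH02Gene19402, 7.59 and 6.69, were 8.83 without 0d replicate 2 and 8.19 without 0d replicate 4.

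At 2d 12 of the 54 lists passed, 3 upward and 9 downward, and 9 of them also with an estimated correlation. The called genes split 41.9% up under TMM scaling but 28.5% up under total-count scaling, which moved the median change of all genes to -0.26 from -0.003, and 26.7% up in the limma fit on log2(FPKM + 1). Under quantile scaling the split was near even, at 48.4% up.

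The comparison of 6d with 0d asks what had changed after 6 days. Genes of DNA replication were higher than at harvest and genes of ribosomal proteins lower. Lists of the raffinose family, upward, and of jasmonate, water channels and lignin monomers, downward, passed with the preset correlation but not with an estimated correlation. Histone H2B.2-like (PH02Gene44357) rose from 38.3 ± 2.56 to 248 ± 7.51 FPKM (log2 change 2.87, SE 0.05, n = 4, edgeR adjusted p = 9.67e-33). Aquaporin PIP1-1 (PH02Gene43726), a plasma membrane water channel, fell from 152 ± 4.17 to 9.41 ± 0.622 FPKM. In all 9629 genes were called, 4207 higher and 5422 lower.

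Of 78 genes of replication and histones 36 rose and 6 fell (median 0.92, camera adjusted p = 0.00667), including a replication protein A 70 kDa subunit B (PH02Gene19819), from 0.319 ± 0.103 to 31.0 ± 1.24 FPKM. Of 9 genes of the raffinose family of sugars, which accumulate in many plants in the cold, 6 rose and 0 fell (adjusted p = 0.0167, and adjusted p = 0.0957 with an estimated correlation). Galactinol-sucrose galactosyltransferase 6 (PH02Gene11640) rose from 9.38 ± 0.530 to 86.1 ± 1.70 FPKM and number 1 (PH02Gene07569) from 0.606 ± 0.217 to 42.9 ± 1.52 FPKM. Of the 7 dehydrin and LEA genes 3 rose and 0 fell, which did not pass the list test (adjusted p = 0.41). A dehydrin DHN1-like gene (PH02Gene07648) was the most abundant of the named members, at 3.65 ± 0.543 FPKM at 0d and 244 ± 12.9 at 6d, and DHN3 (PH02Gene07646) was at least 136-fold higher. NAC transcription factor genes went both ways, with 28 of 78 higher and 21 lower. The list passed upward (adjusted p = 0.0268, but adjusted p = 0.229 with an estimated correlation and 0.0889 under quantile scaling). NAC29-like (PH02Gene19528) rose from 72.5 ± 1.97 to 241 ± 3.38 FPKM and NAC100 (PH02Gene44182) from 56.8 ± 1.71 to 269 ± 6.65 FPKM.

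Of 272 genes of cytosolic ribosomal proteins 63 fell and 2 rose (median -0.60, adjusted p = 1.27e-08), with 40S S12 (PH02Gene15146) down from 59.6 ± 1.88 to 15.5 ± 0.802 FPKM and 60S L31 (PH02Gene22851) from 123 ± 4.39 to 41.3 ± 1.90 FPKM. In the jasmonate list, which holds enzymes and repressors of this wound and defence hormone, 26 of 47 genes fell and 1 rose (adjusted p = 0.00246, but adjusted p = 0.272 with an estimated correlation). TIFY 10c-like (PH02Gene03055) was at 268 ± 4.53 FPKM at 0d and 65.1 ± 0.707 at 6d, and allene oxide cyclase 3 (PH02Gene46743), an enzyme of jasmonate synthesis, at 68.9 ± 2.52 and 3.12 ± 0.453. Aquaporin genes fell in 10 of 16 cases and rose in 1 (adjusted p = 0.0126, but adjusted p = 0.3 with an estimated correlation). A further PIP1-1 gene (PH02Gene26718) changed by -1.49 (SE 0.03). Of 83 genes for enzymes of the lignin monomer pathway 35 fell and 8 rose (median -0.76, adjusted p = 0.0101, and adjusted p = 0.115 with an estimated correlation). A caffeic acid O-methyltransferase (PH02Gene02562) fell from 51.6 ± 0.526 to 3.85 ± 0.320 FPKM and a phenylalanine ammonia-lyase (PH02Gene30511) from 29.3 ± 0.769 to 2.14 ± 0.399 FPKM. Lipid transfer protein genes fell in 19 of 29 cases and rose in 2 (adjusted p = 0.0221, 0.0957 with an estimated correlation and 0.0568 without strays), among them the pEARLI1-like genes PH02Gene50248 (-4.96, SE 0.13) and PH02Gene24250, which held 2 fragments at 6d and was lower by a ratio of 234 (64.4 to 1940; fitted change -7.78, and -9.98 without 6d replicate 3). Expansin genes, whose products loosen walls, fell in 11 of 19 cases and rose in 2 (adjusted p = 0.0448). That call ended with an estimated correlation (adjusted p = 0.3) and without 0d replicate 1 (0.0531), 0d replicate 2 (0.0521), 6d replicate 1 (0.0525) or replicate 3 of every time (0.0507). Expansin-B4 (PH02Gene01650) went from 21.6 ± 0.665 to 0.190 ± 0.131 FPKM and expansin-A10 (PH02Gene00624) from 23.8 ± 1.37 to 3.79 ± 0.510 FPKM. Of 51 antioxidant enzyme genes 14 fell and 3 rose (adjusted p = 0.0184, and adjusted p = 0.0788 with an estimated correlation). A peroxisomal ascorbate peroxidase 3 gene (PH02Gene29154) changed by -2.20 (SE 0.06) and a monodehydroascorbate reductase-like gene (PH02Gene44389) by 1.21 (SE 0.03).

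The largest changes at 6d again involved genes near 0 in a group. DMP2 (PH02Gene26343) reached 40.0 ± 5.08 FPKM, at least 629-fold over 0d, and WIP1-like (PH02Gene11536) was at least 195-fold higher. A polygalacturonase (PH02Gene43221, scaffold 15, 96528185 to 96530854) with 1 fragment at 0d was higher by a ratio of 1020 (182 to 40100), and a beta-D-xylosidase 2 gene (PH02Gene33530) with less than 1 fragment by 884 (78.8 to 17500), the latter not called in the limma fit on log2(FPKM + 5) at 0.531. Pathogenesis-related protein 1 (PH02Gene38178) rose from 0.103 ± 0.130 to 23.7 ± 2.38 FPKM. Aquaporin PIP2-6 (PH02Gene19098, scaffold 24, 15405855 to 15407915), D14 (PH02Gene24299) and a short farnesol/nerolidol synthase gene (PH02Gene10447) had 0 counts at 6d and were at least 664-fold, 414-fold and 113-fold lower. A longer farnesol/nerolidol synthase gene (PH02Gene10446), an enzyme of volatile sesquiterpenes, fell from 78.6 ± 2.35 to 0.0476 ± 0.0411 FPKM. The photosystem II 10 kDa genes PH02Gene08265 and PH02Gene09620 were lower by ratios of 2260 (406 to 89400) and 1270 (308 to 9200). The few counts of PH02Gene43221, PH02Gene33530, PH02Gene08265 and PH02Gene09620 in the lower group lay in 1 library each. Without 0d replicate 4 PH02Gene43221 was at least 257-fold and without 0d replicate 1 PH02Gene33530 at least 108-fold higher, and the fitted change of PH02Gene38178 was 9.05 in place of 7.90. Without 6d replicate 4 PH02Gene08265 was at least 546-fold and without 6d replicate 2 PH02Gene09620 at least 566-fold lower, and the change of PH02Gene10446 was -10.99 in place of -10.40.

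At 6d 19 of 54 lists passed, 6 upward and 13 downward, of which 8 also passed with an estimated correlation. The share of called genes that rose was 43.7% under TMM scaling, 33.6% under total-count scaling, where the median change of all genes was -0.21, and 32.8% in the limma fit on log2(FPKM + 1). Under quantile scaling it was 49.3%.

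The comparison of 20d with 0d asks what had changed after the longest storage. Most cytosolic ribosomal protein genes and photosynthesis genes were lower, and genes of autophagy and proteases were higher. The 40S ribosomal protein S8-like gene (PH02Gene42751) fell from 416 ± 7.75 to 22.8 ± 1.16 FPKM (log2 change -3.87, SE 0.03, n = 4, edgeR adjusted p = 2.74e-42). The atg7 gene (PH02Gene40863) rose from 31.0 ± 1.09 to 323 ± 1.99 FPKM. Of the genes tested 10993 were called, 4876 higher and 6117 lower.

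Of 272 cytosolic ribosomal protein genes 235 fell and 2 rose (median -2.04, camera adjusted p = 1.93e-26). The 60S L5-1 gene (PH02Gene29817) fell from 423 ± 8.08 to 64.9 ± 2.21 FPKM. Photosynthesis genes fell in 58 of 74 cases and rose in 2 (median -3.60, adjusted p = 2.81e-08), the antenna gene PH02Gene49412 to 0.162 ± 0.0841 FPKM. PH02Gene09620 held 2.50 fragments at 20d, a ratio of 823 (234 to 3330) below 0d (fitted change -9.62, and -10.43 without 20d replicate 3). Heat shock protein and chaperone genes fell in 74 of 159 cases and rose in 13 (adjusted p = 0.00156), with the abundant heat shock protein 70 gene PH02Gene35944 down from 618 ± 4.71 to 61.4 ± 1.55 FPKM and PH02Gene32604 to 1.95 ± 0.322 FPKM. Tubulin genes fell in 12 of 21 cases and rose in 2 (adjusted p = 0.00165, but adjusted p = 0.12 with an estimated correlation), with beta-4 (PH02Gene37926) at 1.98 ± 0.149 FPKM and alpha-1 (PH02Gene12444) down from 307 ± 7.41 to 58.7 ± 2.34 FPKM. Of 47 jasmonate genes 28 fell and 3 rose (adjusted p = 0.000811, but adjusted p = 0.218 with an estimated correlation). TIFY 10a (PH02Gene04428) fell from 235 ± 4.08 to 45.5 ± 0.752 FPKM, whereas TIFY 11c (PH02Gene40897) rose from 27.1 ± 0.557 to 150 ± 2.21 FPKM.

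Autophagy genes rose in 23 of 45 cases with 0 falls (median 1.18, adjusted p = 2.34e-09), and the 18h-like gene PH02Gene27630 reached 135 ± 2.83 FPKM. Cysteine and aspartic protease genes rose in 31 of 68 cases and fell in 13 (adjusted p = 0.00622). Their median change was 0.83 but their mean -0.01, as the members that fell did so by more, and the call ended without a filter on low values (adjusted p = 0.151). Cysteine proteinase 1-like (PH02Gene29546) rose from 12.9 ± 0.730 to 207 ± 5.43 FPKM and a vacuolar-processing enzyme-like gene (PH02Gene22160), which activates vacuolar proteins, from 25.3 ± 0.790 to 131 ± 2.61 FPKM. Of 78 NAC genes 35 rose and 18 fell (adjusted p = 0.0101, but adjusted p = 0.155 with an estimated correlation), with NAC104 (PH02Gene26525) up from 31.7 ± 1.53 to 327 ± 4.45 FPKM and NAC29-like (PH02Gene19528) to 316 ± 2.81 FPKM. Laccases, oxidases that polymerise lignin monomers in the wall, rose in 9 of 14 cases and fell in 2, but the list did not pass (adjusted p = 0.183). Of 44 class III peroxidase genes 13 rose and 22 fell (adjusted p = 0.51), with peroxidase 16 (PH02Gene05420) up from 144 ± 1.65 to 336 ± 0.894 FPKM and peroxidase 3 (PH02Gene48469) down from 178 ± 5.47 to 43.9 ± 1.13 FPKM. Genes of sucrose and hexose metabolism also split, 20 of 58 up and 16 down (adjusted p = 0.407; median 0.39, mean -0.03). The sucrose synthase genes PH02Gene02657 and PH02Gene04423 fell from 245 ± 1.52 to 23.2 ± 0.898 and from 129 ± 2.50 to 8.25 ± 0.722 FPKM.

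The beta-D-xylosidase 2 gene (PH02Gene33530, scaffold 1, 3956429 to 3959596), an enzyme that trims xylan, went from less than 1 fragment at 0d to 41.9 ± 1.05 FPKM at 20d, a ratio of 18300 (1640 to 362000). The polygalacturonase PH02Gene43221 was higher by a ratio of 3630 (651 to 143000) and a flavonoid O-methyltransferase-like gene (PH02Gene24614) by 2440 (626 to 8880). Without 0d replicate 1 the bound for PH02Gene33530 was 2240-fold, and without 0d replicate 4 that for PH02Gene43221 was 921-fold and the fitted change of PH02Gene24614 11.87 in place of 11.16. DHN3 (PH02Gene07646), DMP2 (PH02Gene26343) and WIP1-like (PH02Gene11536) were at least 500-fold, 364-fold and 151-fold higher than at 0d. WIP1-like was at 1.72 FPKM in 20d replicate 3 and at 9.96 to 14.4 FPKM in the other libraries of 20d. Among genes with 0 counts at 20d, the farnesol/nerolidol synthase gene PH02Gene10446 (scaffold 15, 41966571 to 41971950) was at least 2540-fold lower, a light-harvesting LHCII type 1 gene (PH02Gene45538) 904-fold and the photosystem II 10 kDa gene PH02Gene08265 696-fold. The corresponding bounds were 299-fold for a PTI1-like kinase (PH02Gene50833), 296-fold for a random slug protein 5-like gene (PH02Gene08388) and 151-fold for the proline-rich protein DC2.15 gene (PH02Gene20333).

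At 20d 14 of 54 lists passed, 4 upward and 10 downward, with 8 of them also passing with an estimated correlation. The share of called genes that rose was 44.4% under TMM scaling, 31.0% under total-count scaling, where the median change of all genes was -0.31, and 31.2% in the limma fit on log2(FPKM + 1). Under quantile scaling it was 49%.

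**Figure D2:**
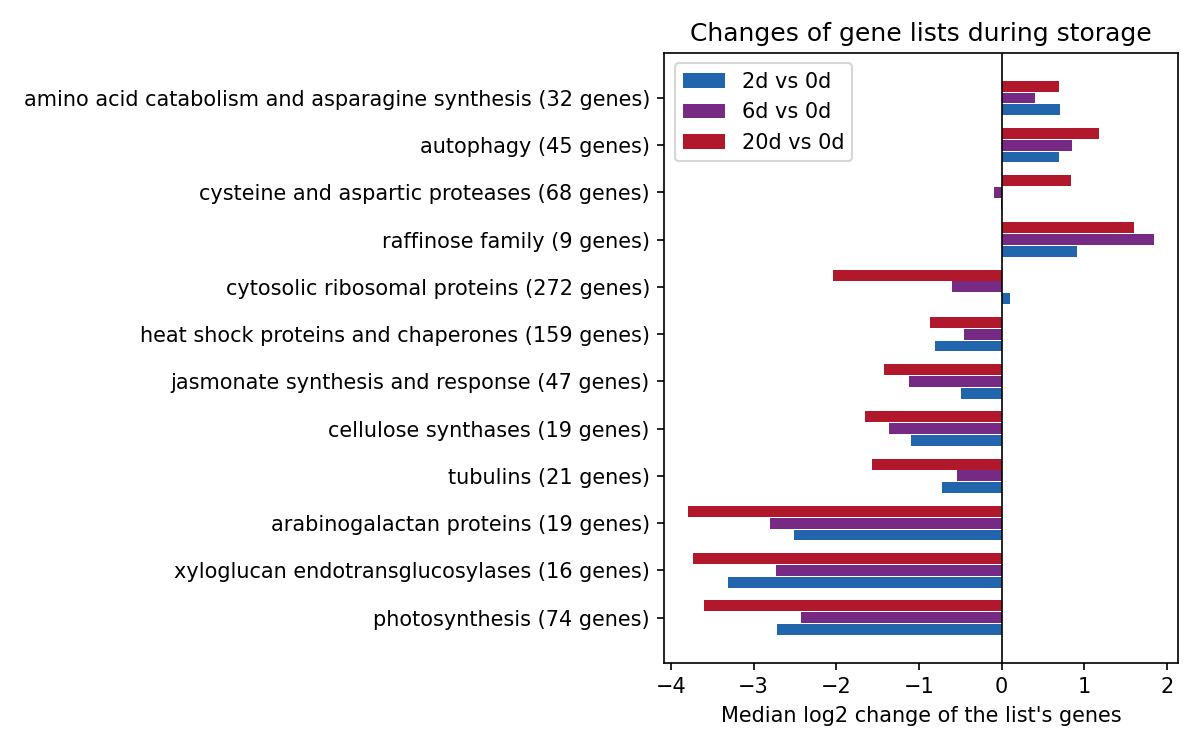
Median log2 change of 12 gene lists at 2d, 6d and 20d against 0d, as horizontal bars coloured by time, with genes at 0 in a group placed at their bound; the number of genes follows each list's name. The ribosomal protein median, 0.11 at 2d and -0.15 there under total-count scaling, was -0.60 at 6d and -2.04 at 20d, while the autophagy median was 0.70, 0.85 and 1.18.

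Enzymes of the lignin pathway are of interest in shoots that are eaten young, and the most abundant gene of each family was followed over the 3 stored times whatever its test. Phenylalanine ammonia-lyase (PH02Gene27016), the entry enzyme, was at 354 ± 3.90 FPKM at 0d and 643 ± 14.6 at 2d (log2 change 1.11, SE 0.04), then 175 ± 14.1 at 6d (-0.84, not called) and 136 ± 3.45 at 20d (-1.06, SE 0.04). Its rise at 2d was below the limit of 1 under 7 of 32 alternatives, with changes from 0.535 under quantile scaling to 0.993 with a mean FPKM of at least 5, and its fall at 6d passed under 6 alternatives, at most to -1.03. Cinnamate 4-hydroxylase 2 (PH02Gene03697) rose at 2d (2.08, SE 0.04) and 6d (1.20, SE 0.05, but 0.99 with limma array weights and 0.91 on log2(FPKM + 5)) and had a change of 0.73 at 20d. The caffeoyl-CoA O-methyltransferase gene (PH02Gene12695) had a change of 1.004 at 2d, which was below the limit under 13 of 32 alternatives. These included total-count scaling (0.75) and the fits without 0d replicate 2 (0.96), 2d replicate 1 (0.997), 2d replicate 2 (0.98) or replicate 2 of every time (0.94). Putative ferulate 5-hydroxylase (PH02Gene08874) was among the most abundant, at 1180 ± 30.5 FPKM at 0d. It had a change of -0.91 at 2d, which passed the limit under 7 of 32 alternatives (-1.03 to -1.43), and fell to 261 ± 4.05 FPKM at 20d. The top gene matched by description to the 4-coumarate-CoA ligase family is described as 4-coumarate-CoA ligase-like 5 (PH02Gene45698). It fell at 20d, from 39.3 ± 1.46 to 7.81 ± 0.431 FPKM. Whether this gene acts in the lignin pathway cannot be told from its description. Cinnamoyl-CoA reductase 1 (PH02Gene01704) had changes of 0.40, -0.66 and -0.39, none of them called, though the last pair passed under quantile scaling at -1.05 and -1.20. Cinnamyl alcohol dehydrogenase (PH02Gene39617) had changes of 0.81, 0.22 and 0.92, and hydroxycinnamoyltransferase 2 (PH02Gene48963) and caffeic acid O-methyltransferase (PH02Gene10900) changes between -0.35 and 0.30. At 20d laccase-19-like (PH02Gene43658) rose from 1.26 ± 0.273 to 22.7 ± 1.53 FPKM (4.50, SE 0.10), and the most abundant cellulose synthase, subunit 5 (PH02Gene08830), from 71.8 ± 1.43 to 123 ± 4.29 FPKM (1.08, SE 0.03, but below the limit under 7 of 32 alternatives, at 0.73 to 0.96).

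**Figure D3:**
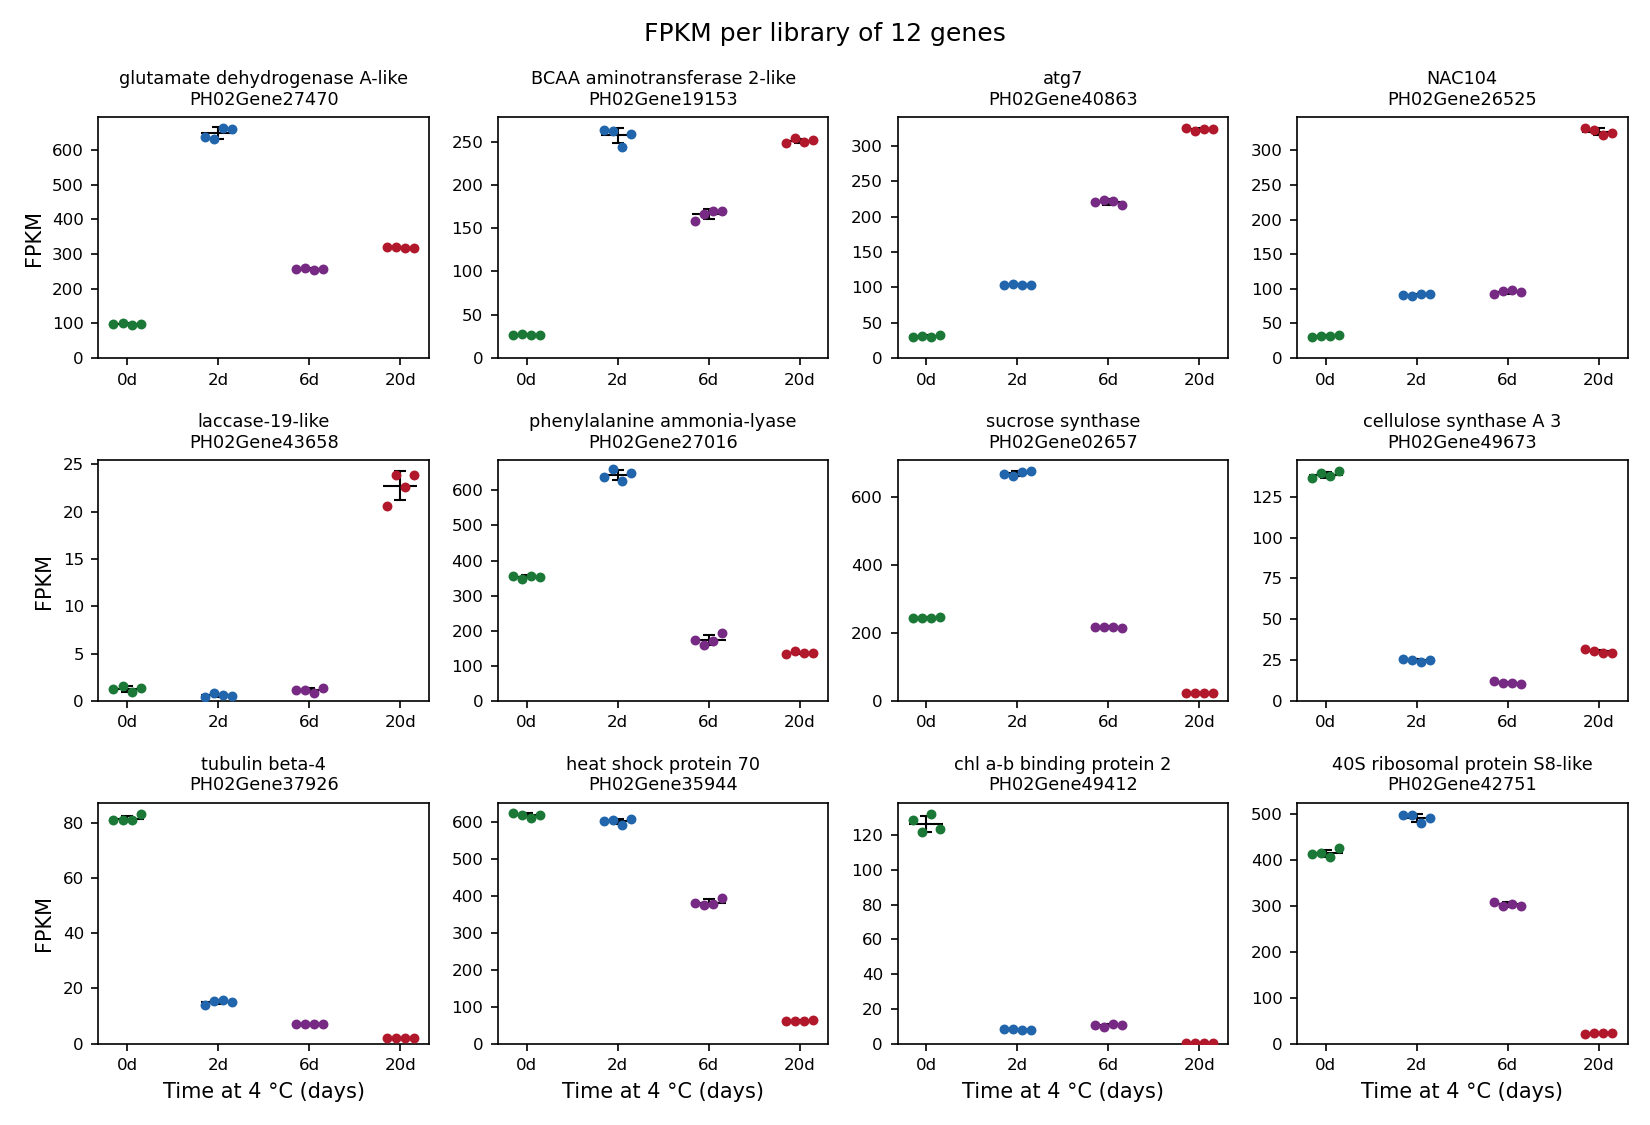
FPKM of 12 named genes in each library against storage time; points are libraries, and black bars the mean ± SD of 4 libraries, with axes from 0 that differ between panels. Sucrose synthase PH02Gene02657 stood at 668 ± 6.10 FPKM at 2d and 23.2 ± 0.898 at 20d, and NAC104 at 327 ± 4.45 at 20d.

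Between 2d and 6d, the first pair of successive stored times, ribosomal protein genes fell and heat shock and replication genes rose. Of 272 ribosomal protein genes 45 fell and 0 rose (median -0.69, camera adjusted p = 3.15e-20). Of 159 heat shock and chaperone genes 29 rose and 9 fell (adjusted p = 0.000909), and of 78 replication and histone genes 28 rose and 0 fell (adjusted p = 0.00337). The list p-values for successive times are given with the preset correlation only. Against 0d fewer lists passed with an estimated correlation, 8 of 19 at 6d. In all 3787 genes were called in edgeR, 1732 up and 2055 down. RHA2A-like (PH02Gene01469) and TIFY 11e (PH02Gene27187), at 0 counts at 2d, were at least 13.8-fold and 6.91-fold higher at 6d. The former missed the limit in the limma fit on log2(FPKM + 5), at 0.329, and the latter in 4 of 32 alternatives, at 0.196 to 0.80. A gene described as a CACTA transposon protein (PH02Gene24871) rose from 0.128 ± 0.0657 to 10.5 ± 0.467 FPKM. Among the falls, PIP2-6 (PH02Gene19098) was at least 8.14-fold lower and PH02Gene08265 lower by a ratio of 31.0 (5.08 to 1260), or at least 7.48-fold without 6d replicate 4. Neither was called in 4 of 32 alternatives, among them the limma fit on log2(FPKM + 1), with log2 changes of -0.28 and -0.52. The random slug protein 5-like gene PH02Gene08388 fell from 9.46 ± 0.527 to 0.394 ± 0.182 FPKM. The limma fit on log2(FPKM + 1) called 1962 genes.

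Between 6d and 20d the fall of ribosomal protein genes was wider, with 163 of 272 lower and 1 higher (median -1.30, camera adjusted p = 9.06e-26). List p-values here again use the preset correlation only. Photosynthesis genes fell in 39 of 74 cases and rose in 3 (adjusted p = 0.000358), genes of replication and histones fell in 29 of 78 and rose in 3 (adjusted p = 0.00716), and cysteine and aspartic protease genes rose in 26 of 68 and fell in 8 (adjusted p = 0.000463). D14 (PH02Gene24299), at 0 counts at 2d and 6d, was at 18.6 ± 0.806 FPKM at 20d, at least 179-fold over 6d. A WAT1-related gene (PH02Gene31810), of a family of membrane transporters, rose from 2.52 ± 0.385 to 279 ± 3.76 FPKM, and a polygalacturonase (PH02Gene14642) from 0.227 ± 0.133 to 20.2 ± 1.53 FPKM. A leaf-specific thionin gene (PH02Gene50531), which encodes a small antimicrobial peptide, was at 409 ± 18.9 FPKM at 6d and had 0 counts at 20d, at least 5180-fold lower. The LHCII type 1 gene PH02Gene45538 and the 60S L13-1-like gene PH02Gene13568 were at least 39.5-fold and 44.4-fold lower, the former not called in the limma fit on log2(FPKM + 5) at -0.445. In all 6726 genes were called in edgeR, 3181 up and 3545 down, and 4475 in the limma fit on log2(FPKM + 1).

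Over the 4 times the F test called 16160 genes, and 14790 were called against 0d at 1 or more stored times. Of these 1767 rose and 2567 fell at all 3. A further 217 rose at 2d and fell at 20d, and 297 fell at 2d and rose at 20d. The direct test of 20d against 2d called each of them. Opposite calls against the same 0d libraries already place the difference past the limit, so this adds no separate support. The 2d and 6d comparisons shared 5924 genes called in the same direction, 2439 up and 3485 down, against 549.8 and 981.8 for independent lists, and 72 went opposite ways. The 2d and 20d comparisons shared 4725, against 637.3 up and 1107.7 down for independent lists, with 514 opposite, and the 6d and 20d comparisons shared 6702, against 822.4 and 1329.6, with 228 opposite. All 3 comparisons use the same 0d libraries, which by itself makes shared calls more frequent. With the 0d libraries divided 2 and 2, a different pair for each comparison, the mean shared counts over 6 divisions were 5839.3, 4693.2 and 6643.3.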

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

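The test of green tissue below was chosen only after the result was seen. The other tests had been written before, but the use of an interval for short transcripts was added after its value was seen. The tests of scaling include total-count scaling, which was itself chosen after the data were seen.

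Whether chance could give the counts was asked with other splits of the same libraries. For the genes called at 2d, 6d and 20d against 0d, and at 6d against 2d and 20d against 6d, 1 of 35 splits, the real one, gave a count as large each time. The real counts were 7777, 9629, 10993, 3787 and 6726 and the highest others 1, 0, 1, 1 and 1. The counts thus depended on the labelled groups. As 1 of 35 is the smallest share these splits can give, they cannot exclude chance. Splits that mix the groups also put the group difference into the spread, which leaves few genes to call. For the 16160 genes of the F test the real split was the only one of 100 with a count as large, with 583 as the highest other. The number of lists passed is not told from chance in this way: 5 of 35 splits gave as many at 2d (12, highest other 12), 5 of 35 at 6d (19, highest other 20) and 2 of 35 at 20d (14, highest other 14). For shared calls, 2 of 100 splits gave as many (5924, 4725 and 6702, highest others 7551, 6697 and 8776), 1 of them the real one. The other split kept the 4 libraries of 0d together, mixed the stored times and gave more shared calls than the real one. It points to the structure of the samples, with 0d apart from all stored libraries. A high shared count thus does not need the stored times as labelled, and these splits do not exclude chance for it.

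With 4 deposited counts taken as 1 fragment, the mean squared difference between 2 libraries of a time was 1.43 times its counting value (median of 24 pairs, range 1.26 to 1.59) for genes with a mean of 20 to 50 deposited counts. It was 1.73 times (1.49 to 2.03) from 200 to 1000 counts, 2.10 times (1.33 to 3) from 3000 to 10000, and 3.52 times (2.00 to 9.52) above 10000. The labels give 6 shoots to a library and call the replicates biological. If the libraries of a time shared shoots or RNA, the SE and adjusted p would leave out differences between lots of shoots, and the splits of libraries would not show it. This reading was made after the values were seen and was not tested.

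Among 210 sets of 4 library values, 17 held a library far from the other 3, and chance alone puts 5% of such sets there. The total count of 2d replicate 3 was 62.44 M, against a mean of 52.81 M in the other 3. Among the named genes at 0d, the FPKM was 71.0 in replicate 2 for PH02Gene02441 (others 76.2), 32.6 in replicate 4 for PH02Gene15190 (34.7), 83.3 in replicate 4 for PH02Gene37926 (81.2), 20.7 in replicate 1 for PH02Gene01650 (22.0), 275 in replicate 3 for PH02Gene03055 (266), 62.4 in replicate 4 for PH02Gene15146 (58.6), 170 in replicate 4 for PH02Gene48469 (181) and 241 in replicate 4 for PH02Gene04428 (233). At 2d it was 67.5 in replicate 3 for PH02Gene28681 (63.9) and 103 in replicate 3 for PH02Gene40863 (104). At 6d it was 17.0 in replicate 4 for PH02Gene11536 (12.3), 225 in replicate 2 for PH02Gene07648 (250.2) and 16.7 in replicate 4 for PH02Gene15146 (15.1). At 20d it was 139 in replicate 1 for PH02Gene27630 (133), 215 in replicate 3 for PH02Gene29546 (204) and 135 in replicate 1 for PH02Gene22160 (130.1).

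Several named genes went opposite ways at 2d and 20d against 0d. They were listed only if the direct edgeR test of 20d against 2d called them too, so that call is no separate support. The log2 change 20d against 2d was 4.81 for TIFY 11c (PH02Gene40897), -4.79 for sucrose synthase (PH02Gene02657), 7.04 for the CACTA transposon protein gene (PH02Gene24871), 8.79 for the WAT1-related gene (PH02Gene31810), 8.39 for the polygalacturonase PH02Gene14642 and -2.17 for phenylalanine ammonia-lyase (PH02Gene27016). The thionin gene (PH02Gene50531) had 0 counts at 20d, a log2 change of at most -10.94 at the floor. Among the lists, the 20d against 2d difference passed with both the preset and the estimated correlation for the cytosolic ribosomal proteins (median log2 change -2.03, estimated adjusted p = 0.000338), photosynthesis (-1.54, adjusted p = 0.0104), autophagy (0.48, adjusted p = 0.0049) and cysteine and aspartic proteases (0.65, adjusted p = 0.0049).

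The fall of cytosolic ribosomal protein genes at 20d was weighed against a loss of short transcripts. A set of 272 other genes matched on length and on FPKM at 0d had a median log2 change of -0.42 (95% bootstrap interval -0.65 to -0.25), against -2.04 for the ribosomal protein genes, which argues against short transcripts as the whole cause. A median above -0.5 had been set before as the sign against it; the interval crosses -0.5 but not -1, the median the cause needed, so a part of the fall stays open. The choice among these scalings is argued against as well, since the highest median under 3 other scalings was -1.99. Median-of-ratios and total-count scaling lowered the median, to -2.07 and -2.36. All of these scalings are relative and would not show a change shared by most genes. A change of the stored shoots with time, which the design names, stays open as a hypothesis and was not tested apart from storage itself.

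The fall of photosynthesis genes from 2d on was weighed against scaling and against a lower share of green tissue in the segments. Under 3 other scalings the highest median at 2d was -1.80, which argues against the choice of scaling. These scalings too are relative. The share of green tissue stays open. Of 24 chlorophyll a-b binding protein genes 23 fell and 0 rose, with a median of -4.82 and an interquartile range of 2.89 on the log2 scale. Their falls were less alike than had been set as the sign for this cause. The rises set as the sign against it were absent. The levels of these transcripts outside green tissue, which would blunt their fall, are not known. Storage itself stays open with it.

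More genes reached 1 FPKM at 0d than at 2d, by 2721.25 on average. With every library thinned to the lowest total the excess was 2726.8 genes, which argues against depth. After rescaling by the TMM factors it was 1978.5 genes, so a few genes taking more of the counts at 2d do not account for most of it. A narrower set of transcripts in stored shoots may remain, as a hypothesis found and tested on these data.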

How the results depend on the processing

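Total-count scaling, limma on log2(FPKM + 1), counts divided by 4, camera on log2(FPKM + 1) or on ranks, and lists without strays were chosen after the data were seen. Counts below are in the order 2d, 6d and 20d against 0d, 6d against 2d, 20d against 6d and the F test. With no filter, 40101 genes tested, they were 12785, 15365, 17228, 5945, 10390 and 24318, and shared calls 9705, 7971 and 10667. With a mean FPKM of at least 5, 16195 genes tested, they were 3934, 5149, 6234, 1862, 3455 and 9299. By adjusted p alone they were 20394, 21492, 21719, 18143, 19362 and 24280. With limma on log2(FPKM + 5), which shrinks the changes of weakly expressed genes, they were 2807, 3808, 5221, 666, 1859 and 7599. The counts for 6d against 2d and 20d against 6d were 1962 and 4475 with limma on log2(FPKM + 1), 1936 and 4168 under quantile scaling, and 1964 and 4476 with array weights. For 6d against 2d alone, treat against a log2 change of 1 gave 2055. The causes of these shifts were not tested. With an estimated correlation 9, 8 and 9 lists passed at 2d, 6d and 20d, the last with the proteasome, which did not pass as reported (adjusted p = 0.0615), and 48, 51 and 53 by directional fry, which does not compare a list with other genes. DESeq2 called 7760, 9554, 10941, 3757 and 6697 genes. Replicate numbers did not pair the libraries (correlations of same-number residuals -0.05 to 0.05), and with replicate number as a block 7777, 9615, 10990, 3787 and 6712 genes were called. Without a library or a replicate number the counts ranged from 7770 to 7803, 9554 to 9635, 10975 to 11030, 3726 to 3798, 6672 to 6731 and 16128 to 16190, and the lists passed from 12 to 13, 18 to 21 and 14 to 16. Treat has no F version, and a fit on the compared groups alone does not apply to the F test, so neither was run for it.

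For 146 changes of named genes, 4672 alternative values gave 4547 with the same direction and call, 59 no longer past the limit, 17 newly past it and 49 reversed. All 49 belong to the most abundant genes of the lignin and cellulose families, whose changes there were not called in edgeR; the cause was not tested. In the order mean FPKM of at least 5, limma with pseudocounts 0.1, 1 and 5, quantile scaling, array weights and total-count scaling, cellulose synthase PH02Gene08830 at 2d (0.08 as reported) had -0.044, -0.176, -0.173, -0.164, -0.172, -0.171 and -0.177. PH02Gene10900 at 20d (0.03) had -0.100, -0.285, -0.277, -0.249, -0.187, -0.274 and -0.291, with -0.003 under median-of-ratios scaling and -0.017 on the compared groups alone. PH02Gene48963 at 2d (0.001) had -0.119, -0.251, -0.238, -0.192, -0.048, -0.241 and -0.251, with -0.013 and -0.012 for the latter pair. Laccase PH02Gene43658 at 6d (0.02) had -0.108, -0.155, -0.093, -0.033, -0.103 and -0.169 under the same settings other than quantile. PH02Gene45698 at 6d (0.15) had -0.028, -0.027, -0.025, -0.010, -0.031 and -0.042 under the limma fits and total-count scaling. PH02Gene01704 at 2d had -0.192 under quantile scaling, and PH02Gene10900 at 6d (-0.04) had 0.028 with no filter. Leaving out libraries gave -0.090 to 0.011 for PH02Gene10900 at 6d, -0.121 to 0.142 for PH02Gene43658 at 6d and -0.075 to 0.069 for PH02Gene48963 at 2d. The depth, about 52 to 65 M deposited counts a library, limits genes near 0: a group with 0 counts gives a bound only, and 1 to 3 fragments give a wide interval.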

Other observations

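The tests of pathways and the choice of genes named here were made after the results were seen.

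Pathways as the deposited table lists them, 124 of at least 10 tested genes, were tested for an excess of called genes by a hypergeometric test, with 744 tests adjusted within each comparison and direction. The test treats genes as independent, so its p-values are too small where genes vary together. The plant circadian rhythm pathway held 36 of 127 genes higher at 2d (14.9 expected, adjusted p = 1.64e-05) and 37 at 6d (19.5 expected, adjusted p = 0.0016). The fixed list of 29 circadian clock genes did not pass, with 4 up and 5 down at 2d (camera adjusted p = 0.944) and 4 up and 8 down at 6d (adjusted p = 0.909). Plant hormone signal transduction held 101 of 514 genes higher at 2d (60.4 expected, adjusted p = 8.32e-06) and 140 at 20d (92.8 expected, adjusted p = 9.34e-06), and ABC transporters, membrane pumps, 28 of 108 at 2d (12.7 expected, adjusted p = 0.00143) and 39 at 20d (19.5 expected, adjusted p = 0.000236). No fixed list of hormone genes passed upward at 2d. The ethylene list had 19 up and 21 down (camera adjusted p = 0.964) and the list of the hormone ABA 8 up and 10 down (0.8). Nicotinate and nicotinamide metabolism held 14, 20 and 22 of 52 genes higher at 2d, 6d and 20d, with adjusted p of 0.0236, 0.0016 and 0.000819. Brassinosteroid synthesis, which makes a growth hormone, held 11 of 18 genes lower at 2d (3.1 expected, adjusted p = 0.000542) and 13 at 6d (4 expected, adjusted p = 0.00024). Lysine biosynthesis held 13 of 25 genes lower at 6d (5.5 expected, adjusted p = 0.0161) and 16 at 20d (6.9 expected, adjusted p = 0.00355). At 20d 33 of 85 genes of fatty acid degradation (15.3 expected, adjusted p = 0.000236), 45 of 135 of glycerolipid metabolism (24.4 expected, adjusted p = 0.000398) and 53 of 182 of the peroxisome (32.8 expected, adjusted p = 0.00208) were higher. The median change of the peroxisome genes, 0.19, became -0.13 under total-count scaling, and that of the hormone genes, 0.03 at 2d and 0.14 at 20d, -0.22 and -0.19.

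Some fixed lists kept their direction at later times. Cellulose synthase genes had 12 falls and 1 rise of 19 at 6d (camera adjusted p = 0.000208) and 11 and 3 at 20d (adjusted p = 0.0101), and arabinogalactan protein genes 17 and 0 of 19 at 6d (adjusted p = 0.000118) and 15 and 1 at 20d (adjusted p = 0.00144). With an estimated correlation and without strays, both missed the limit at 20d (adjusted p = 0.0765 and 0.0503). The list of mitotic cyclins and kinesins, which act in cell division, did not keep its direction. Its median change against 0d was 0.32 at 2d, 0.20 at 6d and -0.13 at 20d. Of its 109 genes 37 fell and 2 rose from 6d to 20d (camera adjusted p = 0.000699, preset correlation). For 20d against 2d the list passed downward with the preset correlation (camera adjusted p = 0.0262) but not with an estimated correlation (0.202). The medians of these lists kept their sign under median-of-ratios, total-count and quantile scaling. Sucrose synthase PH02Gene02657 was at 245 ± 1.52 FPKM at 0d, 668 ± 6.10 at 2d, 217 ± 1.97 at 6d and 23.2 ± 0.898 at 20d (SD, n = 4).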
